A study of Homo sapiens with 6 samples.

How the data were processed

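AGS cells without bacteria (3 libraries) and AGS cells with H. pylori at a multiplicity of infection of 100 for 24 hours (3 libraries) were profiled. Per the labels' protocols, total RNA was extracted with a column kit, stranded libraries were made from messenger RNA with an Illumina TruSeq kit, and paired-end reads were taken on Illumina instruments. The deposited values are FPKM, which the authors computed for each gene and library as fragments scaled to the length of the gene and the depth of the library. The aligner, the counting tool, the annotation and any filter are not given in the sources used here. The submitters' processing notes name the genome builds GRCm38 and mm10, both of mouse, while 16462 of the 16714 listed gene symbols were found in a table of human gene names. Because the build is in doubt and the values carry symbols only, no coordinates are given. The per-library values were identical to the columns of the joint table, which was the one analysed. Mitochondrially encoded genes and some members of the gene lists were not analysed here.

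FPKM keeps the trace of whole fragments. Ratios of low values between libraries fell on ratios of small whole numbers, which gave each library's relative depth, from 0.989 to 1.06 of the first. With a tolerance of 0.005 for a value called whole, fragments were recovered for all 10524 tested genes (100%) and for 93.7% of genes above 0 in any library. Over the listed genes they came to 17900259, 18683782 and 18234673 in the uninfected libraries and 18979012, 17742156 and 18578266 in the infected ones, so depth differed little between the groups. A common factor of a gene's fragments is missed by chance in about 1.70% of genes. On simulated fragments 97.8% of 1895 genes with a mean FPKM of at least 1 were recovered exactly. The FPKM values summed to between 349120 and 359012 in the uninfected and between 316616 and 330874 in the infected libraries. Between 2386 and 2578 genes per library were listed at 0. A few genes that most cells use stand unusually low, RPS10 at 1.63 FPKM against 30.6 for the next ribosomal protein gene in uninfected cells, so a low value can come from the counting of overlapping or near-identical genes.

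Genes with a mean FPKM of at least 1 over the 6 libraries were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a variance trend), two-sided, and p-values were adjusted by the method of Benjamini and Hochberg with a threshold of 0.05. A fold change on this scale understates the change of low genes. The fit had no covariates, since no label says that replicate numbers pair the samples. An exact permutation test of 3 against 3 libraries cannot go below a two-sided p of 0.1 and was not used. Replicates were compared by a chi-square of their recovered fragments, which came to between 2.26 and 9.97 per gene for pairs within a group, where sampling alone gives about 1, so no pair was taken for copies of 1 library.

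The design, the alternatives and 30 gene lists were fixed before the data were examined. They cover NF-kB targets, cytokines and chemokines, bacterial sensors, interferon-stimulated genes, MHC class I, immediate early genes, EGF receptor ligands, matrix proteases, junctions, gastric lineage, mitosis, replication, repair, p53, unfolded protein response, NRF2, metallothioneins, heat shock, hypoxia and glycolysis, cholesterol, autophagy, WNT, YAP, oxidative phosphorylation, mitochondrially encoded genes, ribosomal proteins, histones and 3 sets of markers of other cell types. For each list the members that rose, fell or did not pass were counted. Lists with at least 5 measured members (26 lists) were tested against all other genes with camera of limma at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over those lists, again with an estimated correlation, and with fry, which tests whether a list moves one way without comparing it to other genes. Of the 12 calls made with the preset correlation, none held with an estimated correlation, which ran from -0.13 to 0.85 in groups of 3.

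Genes were named by a rule fixed beforehand: the 10 with the highest and the 10 with the lowest log2 difference among those past the threshold with no overlap of the groups, for each list up to 3 members with the greatest change in the direction most members took and 1 in the other direction, and always CXCL8, NFKBIA, TNFAIP3, CCL20, CDKN1A and HMOX1. Symbols of uncharacterised, antisense, non-coding and readthrough genes were passed over. Some genes that the rule names are not reported here. Gene length was taken from the FPKM divisor and GC content from human transcripts matched by symbol, found for 99.8% of tested genes.

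The alternatives were pseudocounts of 0.1 and 5, no filter and a mean FPKM of at least 5, quantile normalization, rescaling to a common sum, median-ratio scaling, no variance trend, array weights, a replicate block and leaving out each library. Added after seeing the data were limma with voom on the recovered fragments, removal of the trend with gene length, and removal of the trends with length and GC content. The gene test was checked on 10524 simulated genes, of which 200 were changed by a set fold and a further list was shifted by 0.3 on the log2 scale. It found 80% of those changed 1.25-fold and 100% of those changed 1.5-fold, 2-fold and 4-fold, with 6 calls among unchanged genes. The noise was normal, independent between genes and set to the variances of the fit, and most genes were unchanged, unlike in these data. The check therefore does not give the rate of false calls in these data.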

Results

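Gene expression was measured by RNA sequencing in AGS cells, a line of epithelial cells from a human gastric adenocarcinoma. Helicobacter pylori, the bacterium that colonises the stomach, was added at a multiplicity of infection of 100 for 24 hours in 3 samples, and 3 uninfected samples served as the control. The labels call the samples of each group biological replicates without saying how they were grown. The p-values therefore set the difference between the groups against the spread among the 3 libraries within each group, whatever that spread covers. The whole fragments recovered from the deposited FPKM values came to between 17742156 and 18979012 per library. Libraries of one group were far more alike than libraries of different groups: Pearson's r of log2(FPKM + 1) across genes, which are not independent replicates, ran from 0.996 to 0.998 within the groups and from 0.852 to 0.862 between them. The first principal component held 97.3% of the variance and separated infected from uninfected libraries. Values below are mean FPKM ± SD with n = 3 per group, log2 differences are infected minus uninfected on the log2(FPKM + 1) scale with their standard error (SE), and adjusted p-values are from limma.

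The design asks how the transcriptome of AGS cells 24 hours after the bacteria were added differs from that of uninfected cells. The labels give a time for the infected samples only, so a difference of time in culture cannot be told apart from infection. The rises with the greatest log2 difference were those of the stromelysin MMP10, the metal-binding protein MT2A, the hypoxia-responsive gene NDRG1, the common cytokine receptor gamma chain IL2RG, the uridine phosphorylase UPP1, the interleukin 6 receptor IL6R, the cytokine IL24, the epidermal lipoxygenase ALOXE3, the cornified envelope protein SPRR2D and the trefoil peptide TFF2. MMP10 rose from 0.484 ± 0.0715 to 25.8 ± 1.94 FPKM (log2 difference 4.17, SE 0.07, adjusted p = 1.4e-12), IL2RG from 4.35 ± 0.571 to 82.2 ± 1.21, and UPP1 from 4.81 ± 0.155 to 87.3 ± 2.34. IL6R rose from 0.280 ± 0.0571 to 18.0 ± 1.52 FPKM and IL24 from 0.287 ± 0.0354 to 18.2 ± 3.17. ALOXE3 rose from 0.435 ± 0.104 to 17.7 ± 1.34 FPKM and SPRR2D from 1.43 ± 0.314 to 28.4 ± 1.15. The deepest falls were those of the fibrinogen chains FGA and FGG, the claudin CLDN2, PAGE4, REG1A, the transglutaminase TGM2, the fatty acid-binding protein FABP5, the chloride channel CFTR, the spermidine synthase SRM and the NADPH oxidase NOX1. FGA fell from 41.6 ± 1.62 to 0.315 ± 0.114 FPKM (log2 difference -5.02, SE 0.07, adjusted p = 5.1e-13), FGG from 66.7 ± 0.924 to 1.12 ± 0.304, and CLDN2 from 28.6 ± 1.504 to 0.169 ± 0.0385. REG1A fell from 142 ± 5.01 to 5.67 ± 1.04 FPKM, TGM2 from 84.2 ± 2.01 to 3.03 ± 0.241, FABP5 from 183 ± 8.49 to 8.83 ± 0.108, and CFTR from 41.0 ± 1.21 to 1.48 ± 0.130. PAGE4 fell from 45.8 ± 4.35 to 1.11 ± 0.451 FPKM, SRM from 30.3 ± 0.384 to 1.32 ± 0.587, and NOX1 from 12.8 ± 0.860 to 0.0817 ± 0.0409, the last resting on 6 fragments over the 3 infected libraries.

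Across the 10524 genes tested, 9018 passed an adjusted p of 0.05, of which 3088 rose and 5930 fell. At a size of at least 2-fold, 775 genes rose and 1954 fell on the deposited scale, against 1207 and 1195 under median-ratio scaling and 1182 and 1197 under quantile normalization. The infected libraries lay wholly above or below the uninfected ones for 9141 genes (86.9%), where chance gives 10%. The balance of rises and falls depended on scaling. The median log2 difference of the tested genes was -0.28 on the deposited scale, -0.18 after rescaling the libraries to a common sum, -0.01 under quantile normalization (4450 genes rose and 4531 fell) and -0.0017 under median-ratio scaling (4441 rose and 4434 fell). Relative abundance is all that these values carry, and each list median below is therefore also given relative to that of all tested genes. For every measured list fixed beforehand the counts adjusted over the list alone equalled those over all genes, except that 72 ribosomal protein genes fell and 5 cholesterol genes rose when adjusted over the list alone. Every gene picked by the naming rule had its 3 infected libraries on one side of the 3 uninfected ones, apart from TPI1.

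Targets of NF-kB, the transcription factor at the centre of the epithelial response to bacteria, were mostly higher after infection, while several of its best-known chemokine targets were lower. Of 20 measured pathway targets, 14 rose, 4 fell and 2 did not pass, with a median log2 difference of 0.77, which is 1.05 above that of all tested genes (camera adjusted p = 1.3e-04, and adjusted p = 0.26 with an estimated correlation). The inhibitor of apoptosis BIRC3 rose from 11.7 ± 0.761 to 140.2 ± 2.02 FPKM and TNFAIP3, which encodes the NF-kB feedback inhibitor A20, from 11.2 ± 0.280 to 133 ± 12.2. The adaptor TRAF1 rose from 0.0929 ± 0.0352 to 10.5 ± 0.975 FPKM, on 23 fragments in the uninfected libraries, and the inhibitor NFKBIA from 62.5 ± 0.465 to 107 ± 2.47. SOD2, the mitochondrial superoxide dismutase, fell from 6.46 ± 0.229 to 1.22 ± 0.0686.

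All 18 measured cytokines and chemokines changed, 8 upward and 10 downward. The neutrophil-attracting chemokines CXCL3, CXCL1 and CXCL2 fell together, CXCL3 from 36.8 ± 1.40 to 2.70 ± 0.233 FPKM (log2 difference -3.36, SE 0.06, adjusted p = 1.8e-12), CXCL1 from 25.5 ± 0.529 to 1.70 ± 0.425, and CXCL2 from 20.4 ± 0.925 to 1.22 ± 0.256. These 3 are close paralogs whose reads the authors' counting could have divided, and their summed FPKM was 82.7 ± 1.86 in uninfected and 5.62 ± 0.304 in infected cells. CXCL8, the interleukin 8 gene, fell from 19.7 ± 1.52 to 11.5 ± 0.632 FPKM (log2 difference -0.72, SE 0.06, adjusted p = 4.4e-07), and CCL20 from 5.31 ± 0.704 to 1.13 ± 0.234. IL23A rose from 1.15 ± 0.0598 to 9.70 ± 0.852. The list as a whole was not set apart from other genes (camera adjusted p = 0.58, direction up, against a median of -0.42, or -0.14 relative to all tested genes, and a mean of -0.33).

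**Figure D1:**
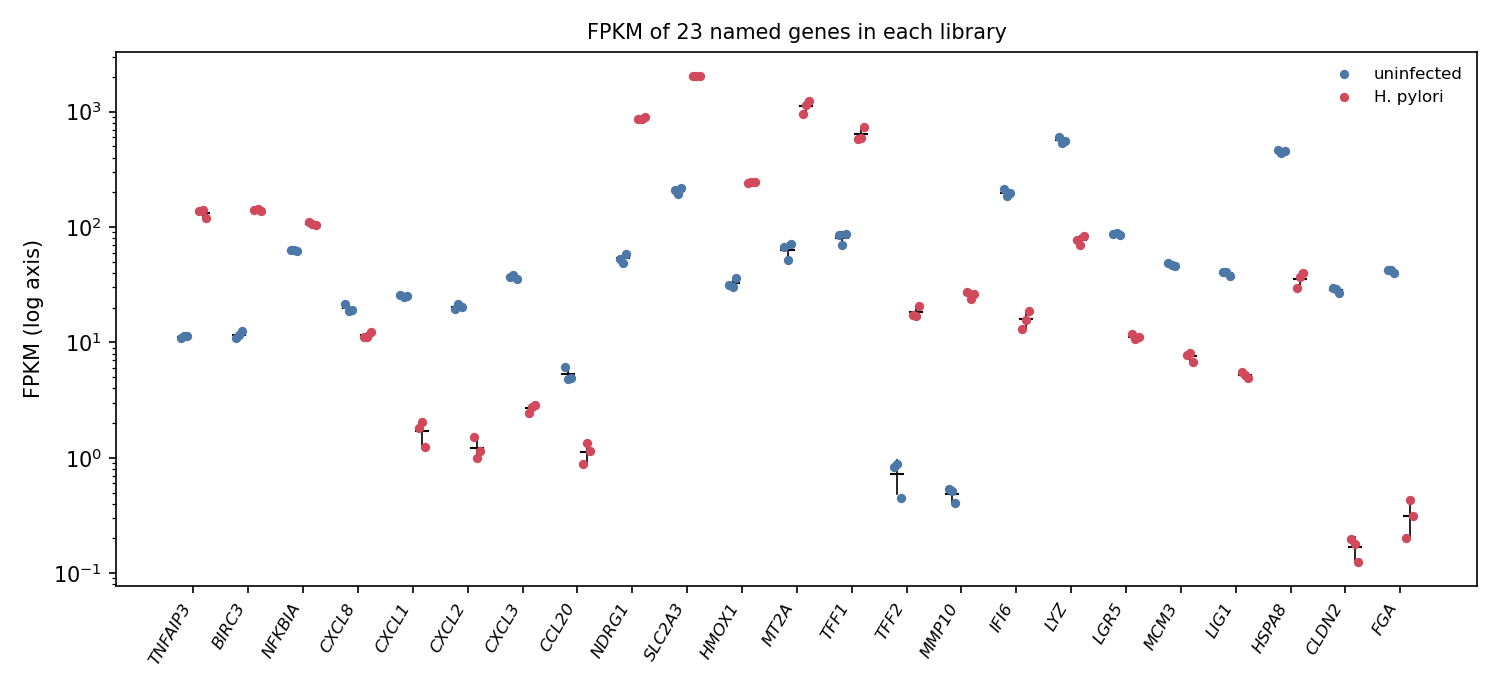
FPKM of 23 named genes on a log axis in each of the 3 uninfected (blue) and 3 H. pylori (red) AGS libraries, with points for libraries, a bar for the group mean and a vertical line for 1 SD either side. The infected libraries lie apart from the uninfected ones at every gene drawn, with TNFAIP3 and BIRC3 above 100 FPKM after infection while CXCL1, CXCL2 and CXCL3 drop below 3 FPKM.

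Genes of hypoxia and glycolysis were higher. Of 23 measured members 22 rose, and the median log2 difference was 2.27, or 2.55 relative to all tested genes (camera adjusted p = 1.7e-12, and adjusted p = 0.26 with an estimated correlation). NDRG1 rose from 53.6 ± 4.81 to 874 ± 21.8 FPKM (log2 difference 4.00, SE 0.06, adjusted p = 7.2e-13), the glucose transporter SLC2A3 from 207 ± 12.3 to 2037 ± 8.24, and the vasodilator peptide gene ADM from 4.47 ± 0.50 to 51.4 ± 1.66. The glycolytic enzyme TPI1 went the other way, from 347 ± 21.9 to 308 ± 18.0 FPKM (log2 difference -0.17, SE 0.06, adjusted p = 0.018), but its libraries overlapped, and under median-ratio scaling its difference was 0.15. The metallothionein list also named the zinc transporter SLC30A1. All 4 measured members of that list rose, too few for a list test. MT2A went from 63.2 ± 10.1 to 1110.3 ± 147 FPKM, MT1X from 73.3 ± 10.4 to 742 ± 146 and MT1F from 3.72 ± 0.914 to 22.3 ± 2.92. Metallothionein genes are near-identical copies, and the share of each is uncertain.

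Other stress responses were divided. Of 17 measured targets of NRF2, the regulator of antioxidant genes, 5 rose and 10 fell (camera adjusted p = 0.86). The heme oxygenase HMOX1 rose from 32.5 ± 3.07 to 243 ± 2.12 FPKM, whereas PGD of the pentose phosphate pathway fell from 75.0 ± 1.24 to 21.1 ± 1.17 and the cystine transporter SLC7A11 from 32.1 ± 2.41 to 10.5 ± 0.834. Of 12 heat shock genes 3 rose and 9 fell (camera adjusted p = 0.15). The constitutive chaperone HSPA8 fell from 453 ± 14.8 to 35.3 ± 5.28 FPKM, HSPE1 from 16.7 ± 1.84 to 2.05 ± 0.593 and HSPB1 from 114 ± 8.20 to 27.5 ± 2.42. The small heat shock protein HSPB8 rose from 25.3 ± 0.739 to 87.2 ± 3.16. In the unfolded protein and amino acid stress list 5 of 26 genes rose and 19 fell, with a median of -1.17, or -0.89 relative to all tested genes (camera adjusted p = 0.13, and 0.037 under quantile normalization). Under median-ratio scaling 8 rose and 16 fell. The serine synthesis enzyme PSAT1 fell from 401 ± 4.68 to 64.5 ± 7.91 FPKM, the folding enzyme PDIA4 from 199 ± 8.02 to 40.2 ± 1.31 and CRELD2 from 19.4 ± 2.08 to 3.43 ± 0.399. PPP1R15A, which encodes the phosphatase subunit GADD34, rose from 84.5 ± 2.38 to 574 ± 32.2.

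Immediate early and MAPK feedback genes were higher as a list. Of 25 measured, 20 rose, 3 fell and 2 did not pass, with a median log2 difference of 1.27, or 1.55 relative to all tested genes (camera adjusted p = 3.4e-08, and adjusted p = 0.27 with an estimated correlation). The AP-1 subunit FOSL1 rose from 17.4 ± 1.07 to 143 ± 8.87 FPKM, the transcription factor KLF4 from 39.7 ± 1.10 to 265 ± 10.9 and JUN from 76.4 ± 2.78 to 391 ± 12.7. FOS fell from 18.6 ± 1.34 to 5.75 ± 0.689. Matrix protease and mesenchymal genes were also higher, with 9 of 12 rising and 2 falling (median 0.86, or 1.14 relative to all tested genes, camera adjusted p = 0.0022, and adjusted p = 0.26 with an estimated correlation). Beside MMP10, the collagen receptor subunit ITGA2 rose from 108 ± 4.31 to 401 ± 6.34 FPKM. The mesenchymal filament VIM fell from 4.56 ± 1.48 to 1.48 ± 0.166. Targets of YAP, the effector of Hippo signalling, went the same way, 12 of 16 rising and 4 falling (median 0.43, or 0.71 relative to all tested genes, camera adjusted p = 0.0022, and adjusted p = 0.55 with an estimated correlation). The tissue factor gene F3 rose from 19.7 ± 1.67 to 157 ± 2.24 FPKM, ASAP1 from 5.49 ± 0.296 to 16.1 ± 1.28 and AMOTL2 from 14.6 ± 0.126 to 36.7 ± 3.31, whereas CCN2, the connective tissue growth factor and a standard YAP target, fell from 40.4 ± 2.48 to 8.81 ± 0.865.

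Among 10 EGF receptor ligands and receptors 6 rose and 4 fell (camera adjusted p = 0.13). EGFR itself rose from 19.5 ± 0.614 to 83.7 ± 9.54 FPKM, its ligand TGFA from 6.00 ± 0.163 to 20.7 ± 0.674 and the receptor MET from 26.3 ± 0.228 to 75.6 ± 0.936. The ligand BTC fell from 3.35 ± 0.201 to 0.741 ± 0.149. The receptors were divided, as ERBB2 fell from 37.0 ± 0.813 to 16.6 ± 0.530 FPKM and ERBB3 from 41.0 ± 1.15 to 16.5 ± 0.791. Of 22 epithelial junction genes 13 rose and 8 fell, with a median of 0.23, or 0.51 relative to all tested genes (camera adjusted p = 0.033, and adjusted p = 0.26 with an estimated correlation), a call that was lost under quantile normalization (adjusted p = 0.13) and at a mean FPKM of at least 5 (adjusted p = 0.054). E-cadherin, CDH1, rose from 3.07 ± 0.0247 to 9.91 ± 0.861 FPKM, the desmosomal plakophilin PKP3 from 42.2 ± 1.59 to 111 ± 0.799 and plakoglobin, JUP, from 118 ± 3.23 to 276 ± 6.11, against the fall of CLDN2.

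Interferon-stimulated genes were lower. Of 29 measured, 24 fell and 2 rose, with a median log2 difference of -1.41, or -1.13 relative to all tested genes (camera adjusted p = 0.0019, and adjusted p = 0.26 with an estimated correlation). Under median-ratio scaling 22 fell and 5 rose. IFI6 fell from 198 ± 13.2 to 15.9 ± 2.92 FPKM, the tethering protein BST2 from 42.9 ± 3.71 to 4.57 ± 0.441 and the RNA sensor OAS2 from 12.3 ± 0.452 to 0.814 ± 0.125. The exonuclease ISG20 rose from 2.89 ± 0.352 to 24.0 ± 0.454. In the MHC class I presentation list 5 of 15 rose and 9 fell (camera adjusted p = 0.88). The peptide transporter TAP2 fell from 12.02 ± 0.235 to 2.67 ± 0.173 FPKM, the immunoproteasome subunit PSMB8 from 39.8 ± 1.92 to 10.6 ± 0.942 and the peptidase ERAP2 from 20.5 ± 0.893 to 8.09 ± 0.177, and HLA-F, one of a family of similar genes, rose from 3.57 ± 0.492 to 6.21 ± 0.269. Bacterial sensors and receptors were mixed, 7 of 19 rising and 11 falling (camera adjusted p = 0.78, direction up, against a median of -0.26, or 0.01 relative to all tested genes), with 8 rising and 8 falling under median-ratio scaling. CEACAM1, of the family bound by the H. pylori adhesin HopQ, fell from 56.9 ± 0.552 to 14.03 ± 0.731 FPKM. Other listed members of that family rose, CEACAM6 from 62.9 ± 1.94 to 92.5 ± 10.5 FPKM and CEACAM5 from 18.0 ± 0.625 to 22.3 ± 4.46. The pyroptosis effector GSDMD fell from 14.7 ± 0.996 to 3.38 ± 0.0482 and the lipopolysaccharide receptor TLR4 from 6.30 ± 0.412 to 1.71 ± 0.0251. ITGA5, of the integrin that the bacterial secretion system can bind, rose from 46.2 ± 2.28 to 222 ± 6.94.

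**Figure D2:**
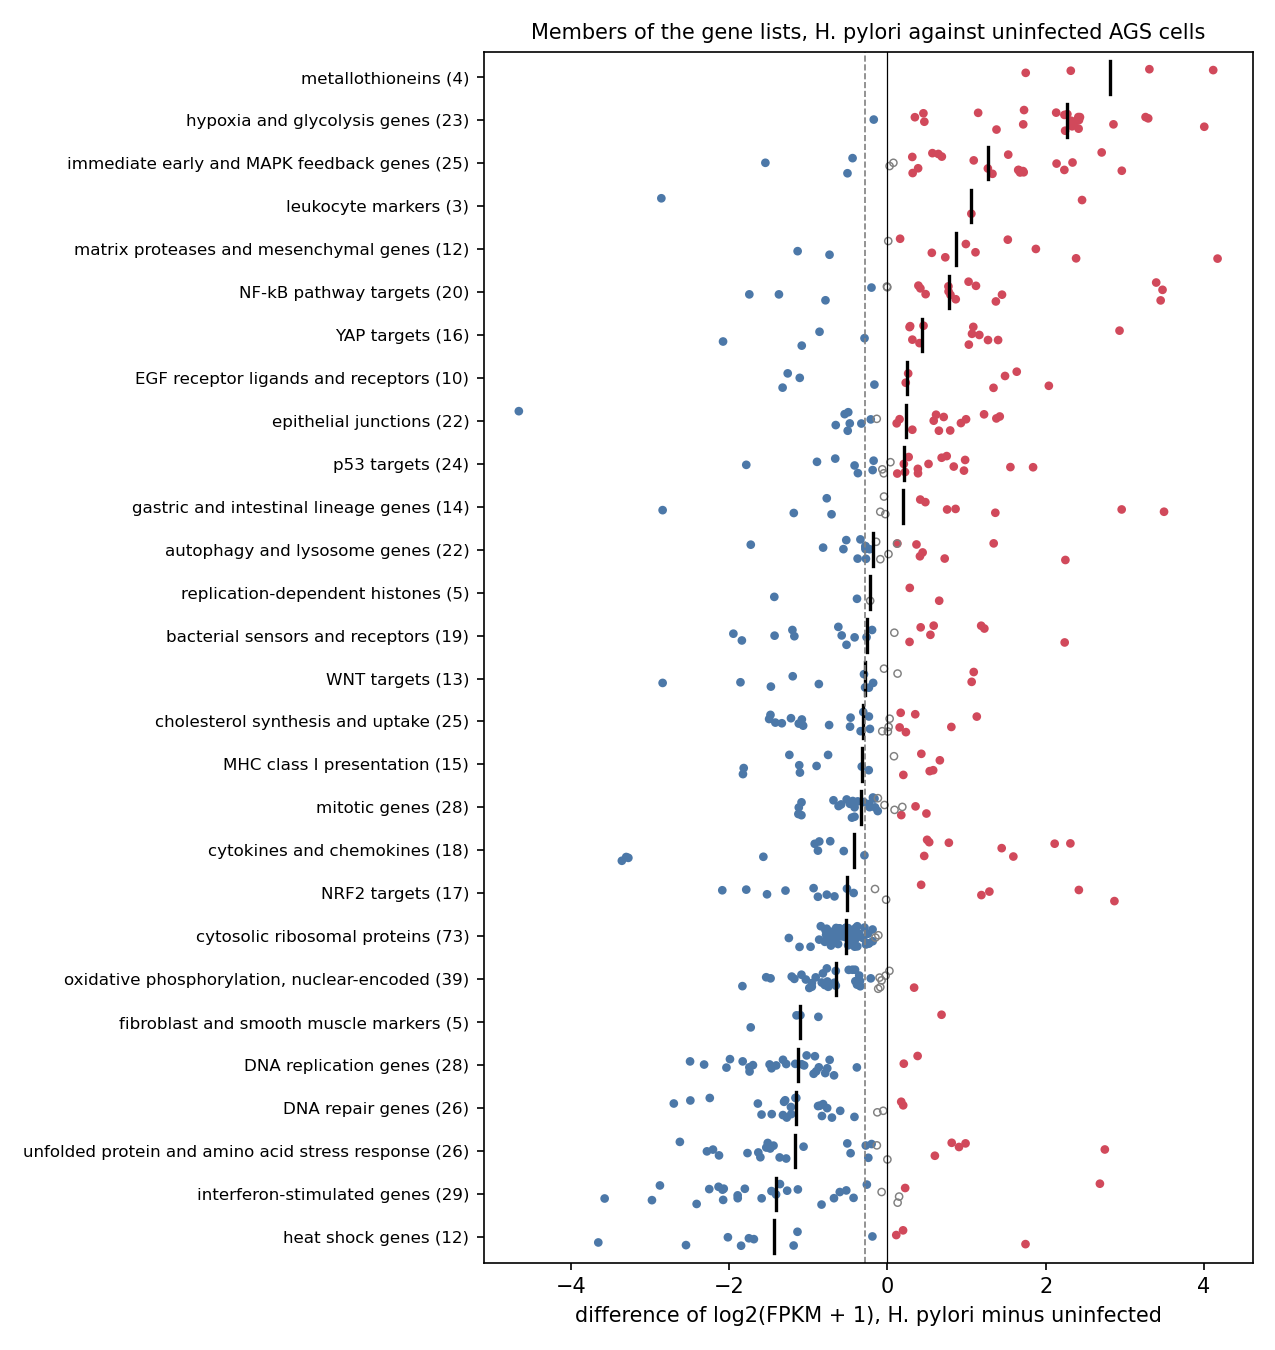
Difference of log2(FPKM + 1), H. pylori minus uninfected, of each measured member of the gene lists with at least 3 of them (number in brackets), red where it rose, blue where it fell and open grey where the adjusted p was 0.05 or more. Black bars are list medians and the dashed line is the median of all tested genes, -0.28; hypoxia and glycolysis genes lie at 2.27 and interferon-stimulated genes at -1.41.

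Genes that copy and repair DNA fell. Of 28 replication genes 26 fell and 2 rose, with a median log2 difference of -1.12, or -0.85 relative to all tested genes (camera adjusted p = 1.3e-04, and adjusted p = 0.26 with an estimated correlation). The helicase subunits MCM3 and MCM4 fell from 47.4 ± 1.62 to 7.61 ± 0.704 and from 36.7 ± 0.575 to 6.57 ± 0.548 FPKM, the thymidylate synthase TYMS from 131 ± 1.85 to 31.3 ± 0.602. The cyclin CCNE2 rose from 5.11 ± 0.593 to 6.94 ± 0.140. Of 26 repair genes 22 fell and 2 rose, with a median of -1.16, or -0.88 relative to all tested genes (camera adjusted p = 0.0019, and adjusted p = 0.26 with an estimated correlation). The DNA ligase LIG1 fell from 39.7 ± 1.64 to 5.26 ± 0.326 FPKM, the base excision enzyme APEX1 from 103 ± 2.64 to 17.5 ± 1.33 and PARP1 from 90.2 ± 0.913 to 18.3 ± 1.76. The mismatch repair gene MSH3 rose from 6.75 ± 0.271 to 7.90 ± 0.414. Mitotic genes changed by less, 21 of 28 falling and 3 rising with a median of -0.34, or -0.06 relative to all tested genes (camera adjusted p = 0.20), and under median-ratio scaling 10 rose and 11 fell. CCNB1 fell from 109.6 ± 4.20 to 49.8 ± 5.42 FPKM, FOXM1 from 33.6 ± 0.657 to 15.0 ± 1.46 and AURKB from 53.9 ± 2.34 to 24.8 ± 0.577. UBE2C rose from 134 ± 6.84 to 189 ± 14.7. Targets of p53 were higher as a list, 14 of 24 rising and 7 falling (median 0.21, or 0.49 relative to all tested genes, camera adjusted p = 0.0097, and adjusted p = 0.27 with an estimated correlation). Under median-ratio scaling 17 of these rose and 4 fell. PLK2 rose from 33.4 ± 1.17 to 122 ± 4.63 FPKM, the stress cytokine GDF15 from 216 ± 3.02 to 636 ± 12.6, the pro-apoptotic BBC3 from 55.6 ± 0.239 to 111 ± 2.23 and the cell cycle inhibitor CDKN1A from 88.8 ± 2.56 to 128 ± 2.73. FDXR fell from 20.6 ± 0.619 to 5.33 ± 1.01. Of 5 replication-dependent histone genes 2 rose and 2 fell (camera adjusted p = 0.78, direction up, against a median of -0.22, or 0.06 relative to all tested genes, that turns to 0.15 under quantile normalization). H1-2 rose from 3.04 ± 1.10 to 5.23 ± 0.917 FPKM and H2BC5 from 2.39 ± 0.168 to 3.12 ± 0.145. H2BC12 fell from 15.9 ± 0.732 to 5.31 ± 0.982.

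Ribosomal protein and respiratory chain genes were lower by smaller steps. Of 73 cytosolic ribosomal protein genes 71 fell and none rose, with a median of -0.52, or -0.24 relative to all tested genes (camera adjusted p = 1.3e-04, and adjusted p = 0.67 with an estimated correlation). RPL6 fell from 213 ± 1.75 to 89.3 ± 5.39 FPKM, RPL23 from 165 ± 9.61 to 76.0 ± 7.23 and RPL4 from 554 ± 17.9 to 282 ± 21.02, and under median-ratio scaling 42 fell and 1 rose. With the length and GC trends removed 24 fell and 10 rose. Of 39 nuclear-encoded genes of oxidative phosphorylation 32 fell and 1 rose, with a median of -0.65, or -0.38 relative to all tested genes (camera adjusted p = 0.0021, and adjusted p = 0.65 with an estimated correlation). Under median-ratio scaling 22 of these fell and 7 rose, with a median of -0.34, and with the length and GC trends removed 20 fell and 10 rose, with a median of -0.21. The ATP synthase genes ATP5MC1, ATP5F1D and ATP5F1A fell from 68.1 ± 5.88 to 18.4 ± 1.58, from 64.6 ± 2.29 to 21.7 ± 2.14 and from 48.5 ± 2.67 to 16.8 ± 0.558 FPKM, and NDUFB8 rose from 117 ± 5.80 to 148 ± 9.58. Shorter genes were lower than longer ones across the transcriptome, and once that trend was removed neither list was set apart (adjusted p = 0.30 for ribosomal proteins and 0.19 for oxidative phosphorylation). The median log2 difference ran from -0.52 in the decile of the shortest genes to 0.09 in that of the longest (Spearman's rho of 0.21 across genes).

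**Figure D3:**
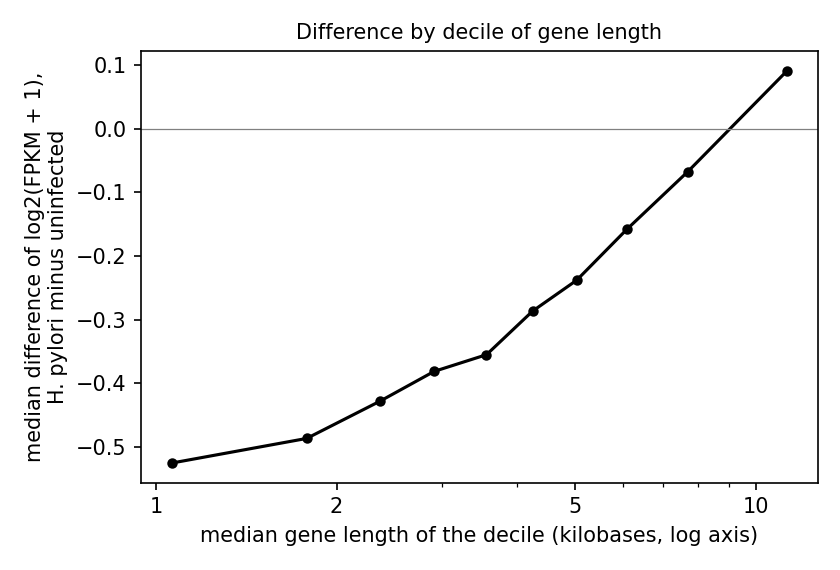
Median difference of log2(FPKM + 1), H. pylori minus uninfected, in each decile of the 10524 tested genes by length, against the median length of that decile in kilobases on a log axis. The medians rise at each step, from -0.52 to 0.09.

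Cholesterol synthesis and uptake genes were divided, 6 of 25 rising and 15 falling (camera adjusted p = 0.52), with 10 rising and 11 falling under median-ratio scaling. LSS fell from 14.8 ± 0.251 to 4.68 ± 0.163 FPKM and FDFT1 from 25.6 ± 0.953 to 8.98 ± 0.706. Of 22 autophagy and lysosome genes 7 rose and 11 fell (camera adjusted p = 0.57, direction up), with a median of -0.18, or 0.09 relative to all tested genes. Under median-ratio scaling the median turned to 0.10, with 10 rising and 4 falling. GABARAPL1 of the autophagosome rose from 26.3 ± 0.932 to 129 ± 10.3 FPKM, whereas the lysosomal membrane gene LAMP1 fell from 182 ± 2.00 to 124 ± 0.475, with a log2 difference of -0.56 that went to -0.04 and lost its call with the length and GC trends removed.

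Among 14 measured gastric and intestinal lineage genes 7 rose and 4 fell (camera adjusted p = 0.14). Besides TFF2, which rose from 0.720 ± 0.234 to 18.4 ± 2.02 FPKM, the gastric trefoil peptide TFF1 rose from 80.8 ± 9.63 to 637 ± 88.6 and the transcription factor GATA6 from 22.1 ± 0.687 to 58.5 ± 3.52. The stem cell marker LGR5 fell from 86.6 ± 1.88 to 11.2 ± 0.468 FPKM (log2 difference -2.84, SE 0.05, adjusted p = 1.1e-12). LGR5 is also a WNT target, and of 13 such targets 9 fell and 2 rose (camera adjusted p = 0.52), with a median of -0.28, or -0.0050 relative to all tested genes. Under median-ratio scaling the median turned to 0.03, with 4 rising and 5 falling. NKD1 fell from 11.3 ± 0.430 to 2.39 ± 0.301 FPKM and RNF43 from 49.4 ± 1.66 to 17.2 ± 1.23, both inhibitors in that pathway, and MYC rose from 45.0 ± 1.38 to 97.1 ± 6.52.

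Markers of other cell types were sparse. Of the 14 leukocyte markers 3 reached the level for testing: CD68 rose from 9.85 ± 0.873 to 58.8 ± 5.35 FPKM, CSF1R from 1.16 ± 0.0438 to 3.51 ± 0.138. The lysozyme gene LYZ fell from 563 ± 31.4 to 76.9 ± 6.46. CD68 is a lysosomal protein and lysozyme a secreted one, and epithelial cells can express both. Of 5 measured fibroblast and smooth muscle markers 4 fell and 1 rose (camera adjusted p = 0.42). DES fell from 9.49 ± 0.101 to 2.17 ± 0.213 FPKM, ACTA2 from 6.01 ± 0.767 to 2.17 ± 0.468 and TAGLN from 30.6 ± 1.21 to 13.7 ± 0.302. COL1A1 rose from 3.51 ± 0.0795 to 6.25 ± 0.151. No endothelial or erythroid marker among those listed reached the level for testing, and the mitochondrially encoded genes were not analysed here.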

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

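The trend removals and the voom fit were chosen after seeing the data. Of 2383 values of the 126 named genes under the alternatives, 2373 kept their direction and side of the threshold, 7 lost their call and 3 reversed. A value counts as reversed when its sign turned, whether or not it passed the threshold. All 3 that reversed were TPI1, at -0.17 in the main setting, which went to 0.15 under median-ratio scaling, 0.26 with the length trend removed and 0.32 with the length and GC trends removed. TPI1 also lost its call without a filter (adjusted p = 0.052), after rescaling to a common sum (-0.04), and without uninfected replicate 1 or 3 or H. pylori replicate 1 or 2 (-0.16 to -0.14), and LAMP1 lost its call with the length and GC trends removed (-0.04). Leaving out each library gave between 8758 and 8987 genes past the threshold. The count of genes moved by less than 1.5 times in every alternative, with 9095 under voom on recovered fragments (3127 rose, 5968 fell).

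The genes past 2-fold moved more. With a pseudocount of 5, 448 rose and 910 fell, with quantile normalization 1182 and 1197, and with median-ratio scaling 1207 and 1195. With the length trend removed 1147 fell and with the length and GC trends removed 1113 fell, and the lists called lower went from 5 to 3 in each. Those removals also evened the split, to 4299 rising and 4520 falling and to 4250 and 4526. The pseudocount shrinks low genes by construction, and a scaling moves all genes of a library together. The lists called went to 0 higher and 0 lower with an estimated correlation and to 16 lower under fry, which asks another question. Of 492 list tests under alternatives 484 stayed on their side, 6 were lost (epithelial junctions under 2 settings, and ribosomal proteins and oxidative phosphorylation under both trend removals) and 2 were gained, the latter being mitotic genes without a filter (adjusted p = 0.041) and the unfolded protein list under quantile normalization (adjusted p = 0.037). Without a filter, metallothioneins and leukocyte markers, with under 5 members measured in the main setting, could also be tested, and metallothioneins were called higher (adjusted p = 9.4e-04) while leukocyte markers were not (adjusted p = 0.11). The correlation of libraries went to 0.994 within and 0.845 between groups with a pseudocount of 0.1, and to 0.793 between groups at a mean FPKM of at least 5. For the moves not named as following from construction, the cause was not tested.

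The replicate block gave 8998 genes past the threshold, 3080 rising and 5918 falling, with no named gene or list changing its call. No pairing by number was seen. Deviations of same-numbered libraries from their group means correlated at -0.07, 0.09 and -0.03. Of the 6 libraries, 2 correlated best with the one of their own number. With 3 libraries per group these deviations have too little freedom to exclude a pairing. Depth limits the lowest genes, such as NOX1 with 6 and TRAF1 with 23 fragments in the group where each was low.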

Other observations

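The 5 lists of the first paragraphs were written after the greatest changes had been seen and leave out the genes that prompted them, and 4 of them were tested. Leaving those genes out does not make the lists independent of them, so these results may partly restate the changes first seen. The squamous list keeps SPRR1A and SPRR2A beside the omitted SPRR2D, and the hepatocyte-type list keeps FGB beside the omitted FGA and FGG. The tests of paralogs and of short-lived transcripts below were also chosen after the result was seen. Ribosome biogenesis factors fell, 36 of 40 with 2 rising, and their median stood at -1.42 relative to all tested genes (camera p = 2.2e-07, adjusted over the lists 8.7e-07, and adjusted p = 0.17 with an estimated correlation). MYBBP1A fell from 17.9 ± 0.556 to 1.33 ± 0.167 FPKM, MRTO4 from 22.0 ± 0.592 to 1.86 ± 0.265 and DKC1, the pseudouridine synthase of the box H/ACA particles, from 45.4 ± 0.533 to 8.05 ± 0.441, while fibrillarin, FBL, was at 260.1 ± 9.13 and 269 ± 5.27 and did not pass. Of 20 cytosolic tRNA synthetase genes 17 fell (18 adjusted over the list alone) and 1 rose, at -0.71 relative to all genes (camera p = 0.0017, adjusted 0.0023, and adjusted p = 0.19 with an estimated correlation), with IARS1 falling from 159 ± 1.09 to 49.0 ± 1.80. Of 34 chaperonin and proteasome subunits 28 fell and 5 rose, at -0.42 relative to all genes. That size leaves a shared fall of the pooled list open (camera p = 0.0034, adjusted 0.0034, and adjusted p = 0.30 with an estimated correlation). Every listed chaperonin subunit fell on the deposited scale, with log2 differences from -2.14 (CCT5) to -0.62 (CCT6A). All 5 that rose were proteasome subunits. CCT5 fell from 110.1 ± 2.81 to 24.2 ± 0.844, while PSMC6 rose from 34.7 ± 0.743 to 49.3 ± 0.25. Under median-ratio scaling 22 chaperonin and proteasome subunits fell and 7 rose, and 15 tRNA synthetase genes fell and 4 rose. With the length and GC trends removed the medians went from -0.70 to -0.28 and from -0.98 to -0.54, where that of all tested genes was -0.02.

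Squamous and cornified envelope genes went up, 13 of 22 measured rising and 7 falling, at 1.05 relative to all genes (camera p = 6.2e-04, adjusted 0.0012, and adjusted p = 0.17 with an estimated correlation). S100A2 rose from 6.83 ± 0.959 to 53.4 ± 1.56 FPKM, EMP1 from 13.2 ± 0.564 to 58.3 ± 3.26 and SPRR1A from 0.493 ± 0.143 to 9.57 ± 0.876, whereas S100A9 fell from 10.3 ± 0.931 to 1.33 ± 0.415. Of 4 measured hepatocyte-type secreted proteins 3 fell, FGB from 9.14 ± 0.135 to 0.225 ± 0.0945 FPKM, too few for a test, with a median of -1.36 relative to all genes. The rise of the hypoxia and glycolysis list kept a median of 2.52 with the length and GC trends removed and of at least 2.40 under the 3 scalings.

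More genes fell than rose on the deposited scale. Rescaling the libraries to a common sum left the median log2 difference at -0.18, so the total of the FPKM values accounts for part of the fall and not the whole. Under median-ratio scaling, which takes the middle gene as unchanged, the difference is gone by construction, and no external standard was used here that would place the whole transcriptome. Of the 10 splits of the 6 libraries into 3 and 3, only the real one gave 9018 genes with limma. The highest of the others gave 0, with 9 genes at an unadjusted p under 0.05 and 0 under voom. Every other split mixes infected and uninfected libraries on each side, which puts the difference between the groups into the spread. The 0 calls there were bound to follow, and no conclusion is drawn from them. With 10 splits a share under 0.05 cannot be reached.

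Longer genes rose relative to shorter ones. GC content as the sole source is argued against by a rho with length of at least 0.13 within each of 5 GC quintiles. Genes of low expression as the sole source are argued against by a rho of 0.25 among the 3201 genes with a mean FPKM of at least 20. Expression level was not held constant among those genes, so its part in the trend stays open. A difference in library preparation stays open: the group mean slopes on length differed by 3.63 times the greatest range within a group, but the groups cannot be told apart from a batch of preparation, since no label gives one. A shift in the transcripts themselves after infection may also give such a trend and was not tested.

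CXCL1, CXCL2 and CXCL3 fell while other NF-kB targets such as TNFAIP3 rose. Reads passing between the 3 paralogs would leave their sum level, but the sum fell, at -3.88 on the log2 scale. Removing the length and GC trends left each of the 3 genes at -2.75 or lower. A general loss of short-lived transcripts in the infected RNA stays open: the immediate early list, also of short-lived transcripts, stood 1.55 above all genes, but a stimulus induces such genes, which would mask a loss. No biological explanation was tested for this split.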
